A study of Mus musculus with 4 samples.

How the data were processed

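Kidney RNA of 8-week-old male C57 mice was compared between animals injected with cisplatin at 30 mg/kg and animals injected with physiological saline. Per the labels' protocols, 18 mice were divided into 3 groups, and cisplatin was given 24 h or 48 h before the animals were killed. Which of these times the cisplatin libraries come from is not given in the sources used here. Total RNA was treated with DNase, depleted of ribosomal RNA and made into directional libraries, which were sequenced as paired reads of 150 nt on an Illumina instrument, per the labels' protocols. The series' design text calls the 2 libraries of each group biological replicates.

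The main input was the authors' deposited table of raw read counts per gene, with 29190 genes and 1 column per library. A table of FPKM values (fragments scaled by transcript length and by the mapped fragments of the library) deposited by the authors for 29157 of these genes served as an alternative. The 33 genes present only among the counts had at most 2 counts in any library. GRCm38, TopHat2, bcl2fastq and edgeR are named, without versions, per the submitters' processing notes. The counting program, its use of strand, its handling of reads that fit several genes and the annotation release are not given in the sources used here. Each group was taken from the treatment label, and no column was left unmapped.

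Library totals were 20662475 and 23150274 counts for cisplatin replicates 1 and 2, and 21483564 and 27122403 for saline replicates 1 and 2. A floor of 3 counts corresponded to between 0.111 and 0.145 CPM (counts relative to the library total) before scaling. Intervals and floors cover counting error only, because PCR copies were not marked with molecular identifiers. The count totals were 60.9 to 67.0% of the fragment totals that the FPKM values imply. This estimate used 838 genes with the same identifier version in the annotation, and FPKM followed from count and exon length within 1% for 53.3% of them. The FPKM scale thus differed from the total of the count table.

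Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes with low counts were removed with filterByExpr, libraries were scaled by TMM (trimmed mean of M values), and the quasi-likelihood F test compared cisplatin with saline over all 4 libraries, with 2 residual degrees of freedom. TMM factors were 1.15 and 1.12 for cisplatin and 0.86 and 0.90 for saline. P-values were adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. Abundances are TMM-scaled CPM, given as mean ± SD of the 2 libraries. A log2 fold change is cisplatin over saline, with a standard error obtained from the fitted value and its F statistic. A change of total RNA per cell shared by all genes is not visible on this scale.

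Before the data were examined, 32 gene lists were fixed, holding 862 distinct genes of kidney segments, other cell types and stress pathways. Each list was tested with limma 3.58.1 camera on log2 CPM with a prior count of 2, at a preset correlation of 0.01 between genes and again with an estimated correlation. Every list had at least 5 tested members. The rule for named genes was also fixed beforehand. It took Tnf and XLOC_032768, both of the series' title, with Havcr1, Lcn2, Cdkn1a and Slc34a1. It added the 8 largest rises and 8 largest falls among called genes with a mean of at least 5 CPM and no overlap between groups, up to 4 members per list with the smallest p, and the Tnf receptors. XLOC_032768, a long noncoding RNA, was not analysed here.

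Replicates were compared before averaging. The chi-square of counts over its degrees of freedom was 12.5 between the cisplatin libraries and 40.3 between the saline libraries, so neither pair agreed within sampling noise. The biological coefficient of variation was 6.4%, which is low for separate animals. Whether tissue of several mice was pooled in a library is not given in the sources used here, so SDs, standard errors and p-values describe the spread between libraries. Coordinates, strand, exon lengths and spans came from GENCODE M21, on GRCm38. Without their version suffix 99.2% of the deposited identifiers matched it, and 45.1% matched with it.

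Alternatives were size factors by relative log expression, upper-quartile scaling, library size without a composition factor, no filter, a filter of 1 CPM in 2 libraries, a replicate block, and each library left out. Other tests were DESeq2 1.42.0, edgeR's exact test, and limma-trend on log2 of FPKM plus a pseudocount of 0.1 or 1. Fits without ribosomal RNA rows, fits on protein-coding genes alone and a test against a 2-fold change (glmTreat) were chosen after seeing the data. Python 3.11.15 with scipy 1.17.1 served for permutation tests and rank correlations, and matplotlib 3.10.9 for plots.

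The tests were run first on simulated counts for the cisplatin against saline comparison, drawn from the libraries' own means and sizes over 17419 genes. Of 50 genes changed at each size, edgeR's quasi-likelihood test recovered 64% at 1.5-fold, 74% at 2-fold, 94% at 4-fold and 100% at 8-fold. It called 13 of 17189 unchanged genes. With so many of the 17419 genes unchanged, the simulation does not test scaling, calls or signs where most genes differ. In the real libraries 73.6% of tested genes were called. For a raised list among 17103 genes, camera gave p = 9.9e-45 at the preset correlation and p = 0.00449 with an estimated correlation. Of 200 unchanged lists, 3 and 0 had p under 0.05, respectively. The partial rank correlation returned -0.155 for a simulated effect of genomic span and -0.019 for exonic length, which had no effect, over 28947 genes.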

Results

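Mouse kidney RNA was measured in 4 libraries, 2 after cisplatin and 2 after saline, with 20662475 and 23150274 counts in the cisplatin libraries and 21483564 and 27122403 in the saline libraries. Cisplatin is a platinum drug that crosslinks DNA and injures the kidney, where tubule cells take it up. The design asks which kidney transcripts differ after cisplatin, and the series' title directs attention to apoptosis of tubule cells and to Tnf, which encodes the inflammatory cytokine TNF-alpha. The libraries of a group correlated at r = 0.993 (cisplatin) and 0.992 (saline) over log2 CPM, and those of different groups at 0.892 to 0.894. The first principal component held 93.4% of the variance and separated the groups, and the second, with 4%, separated the saline libraries.

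Cisplatin kidneys carried far more transcript of tubule injury genes and of the cell cycle inhibitor Cdkn1a, and far less of the transporters of the proximal tubule, the segment that reabsorbs most filtered solutes. Cdkn1a rose from 2.18 ± 0.399 to 330.4 ± 19.8 CPM (mean ± SD, n = 2), and Slc34a1, the main phosphate transporter of the proximal tubule, fell from 2272 ± 12.2 to 483 ± 14.7 CPM. Of 17419 genes tested, 12820 (73.6%) were called by edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05, with 6487 higher and 6333 lower after cisplatin. At least a 2-fold change was found for 6148 of these, 3350 higher and 2798 lower. In 86.3% of the tested genes the cisplatin and saline libraries did not overlap, against 33.3% expected by chance for 2 against 2. The split by direction depended on the scaling, since with library size alone 9110 genes were higher and 4207 lower. With limma-trend on FPKM, where the test, the filter and the number of genes tested (28436) differed too, 7258 were higher and 3804 lower at a pseudocount of 0.1, or 7319 and 3784 at a pseudocount of 1. The median log2 fold change of the tested genes was 0.04 with TMM, 0.16 with upper-quartile scaling, 0.41 with library size alone, and 0.28 and 0.15 with FPKM at the respective pseudocounts, so each change is relative to this level.

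Each of the 145 named genes that were tested passed the edgeR quasi-likelihood test, the largest Benjamini-Hochberg adjusted p being 0.00148, and in each the groups did not overlap. Most of them were picked for a small p, or for a call without overlap, in these same data. Their passing was thus largely set by the selection, and of all tested genes 73.6% were called and 86.3% did not overlap. Camera called 19 of the 32 gene lists at the preset correlation, 10 higher and 9 lower. With an estimated correlation it called 0 of the 32 lists, at adjusted p of 0.172 or more, although 8 had an unadjusted p under 0.05. These values are given with each called list. The estimate was 0.01 for the proximal tubule list, 0 for p53 targets and -0.03 for tubular injury markers, at or below the preset. Correlation between genes thus does not account for the loss of those calls, whereas the estimate reached 0.81 for the mitochondrially encoded list. The fry test of limma, which asks whether members move on balance in 1 direction and makes no comparison with other genes, gave an unadjusted p under 0.05 for 30 lists. No list median changed sign under upper-quartile scaling or library size alone, although that of the clock genes went to 0 with the latter. Adjusted over the list alone, the numbers of rising and falling members equalled those over all genes tested in 29 of the 32 lists, and the exceptions are given where those lists are described.

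Tnf (ENSMUSG00000024401.12, chromosome 17, 35199381 to 35202007, minus strand, GRCm38) rose from 0.19 ± 0.0372 to 2.99 ± 0.352 CPM (SD, n = 2). Its log2 fold change was 3.97 with a standard error of 0.41 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 3.49e-08). The saline level rested on 4 counts in each library, against 65 and 84 counts in the cisplatin libraries. Both receptors rose as well, Tnfrsf1a from 25.1 ± 2.98 to 71.9 ± 1.75 CPM and Tnfrsf1b from 5.28 ± 1.26 to 24.2 ± 0.46 CPM. All 31 tested members of the list of TNF and NF-kB response genes rose, with a median log2 fold change of 2.22 (camera adjusted p = 2.37e-10; adjusted p = 0.185 with an estimated correlation), and adjusted over the list alone 31 rose. The list held 37 genes, and the others were not tested. The filter can keep a gene through the libraries of a single group. Lif, a cytokine of the interleukin-6 family, rose from 0.456 ± 0.109 to 35.6 ± 2.5 CPM. The neutrophil attractant Cxcl1 rose from 1.66 ± 0.0272 to 29.4 ± 0.207 CPM, and Nfkb2, a subunit of NF-kB, from 8.62 ± 0.097 to 56.8 ± 4.81 CPM. In the same libraries 15 of 25 macrophage and monocyte markers rose and 2 fell (median 0.98; adjusted p = 0.21 with an estimated correlation), and 12 of 12 tested neutrophil markers rose (median 4.32; adjusted p = 0.249 with an estimated correlation).

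**Figure D1:**
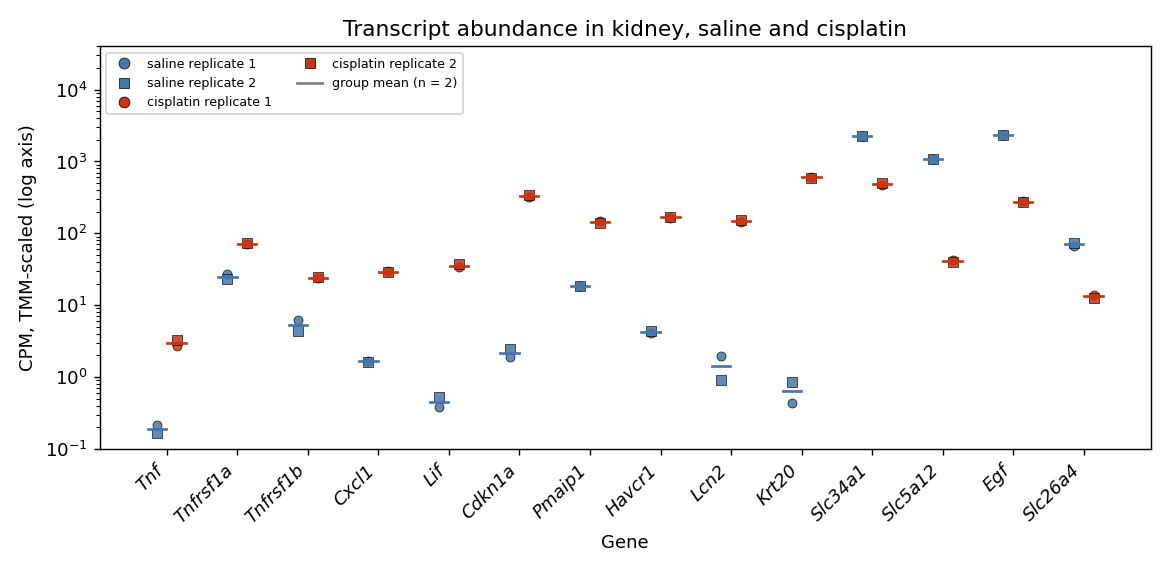
TMM-scaled CPM (log axis) of 14 genes in each library, with saline in blue, cisplatin in red, circles for replicate 1, squares for replicate 2 and bars for group means (n = 2). Tnf moves from a mean of 0.19 to 2.99 CPM and Slc34a1 from 2272 to 483 CPM, and in all genes shown the groups do not overlap.

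All 27 tested markers of tubular injury rose, 26 of them at least 2-fold, with a median log2 fold change of 2.94 (camera adjusted p = 7.1e-11; adjusted p = 0.172 with an estimated correlation), and adjusted over the list alone 27 rose. Havcr1 (ENSMUSG00000040405.11, chromosome 11, 46735080 to 46779578), which encodes kidney injury molecule KIM-1, rose from 4.27 ± 0.221 to 167 ± 2.03 CPM, a log2 fold change of 5.28 (SE 0.08). Lcn2 (ENSMUSG00000026822.12, chromosome 2, 32384633 to 32388252), which encodes the iron-siderophore binder NGAL, rose from 1.42 ± 0.74 to 148 ± 7.72 CPM, a log2 fold change of 6.76 (SE 0.13). Lcn2 is also a neutrophil granule gene and stands in the neutrophil list. All 12 tested members of that list rose in these libraries (median 4.32), and all 45 tested proximal tubule genes fell (median -2.53). The tight junction gene Cldn4 rose from 7.04 ± 0.452 to 172 ± 0.566 CPM, and Tnfrsf12a, the receptor of the cytokine TWEAK, from 7.98 ± 0.881 to 154 ± 8.53 CPM.

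Targets of the DNA damage regulator p53 rose in 29 of 35 cases and fell in 5, with a median log2 fold change of 2.78 (camera adjusted p = 1.2e-07; adjusted p = 0.172 with an estimated correlation), and adjusted over the list alone 29 rose and 5 fell. With library size alone 30 rose and 2 fell. Cdkn1a (ENSMUSG00000023067.11, chromosome 17, 29090976 to 29100727), which encodes the cyclin-dependent kinase inhibitor p21, had a log2 fold change of 7.22 (SE 0.1; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 1.47e-20). A gene on the opposite strand overlaps it, and whether counting used strand is not given. The polo-like kinase gene Plk2 rose from 25.5 ± 1.69 to 314 ± 6.44 CPM, the stress gene Trp53inp1 from 97.0 ± 0.611 to 784 ± 5.73 CPM, and the antiproliferative gene Btg2 from 29.99 ± 1.97 to 276 ± 8.37 CPM.

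Genes of the apoptosis machinery changed in both directions, as did all 17419 tested genes, of which 6487 rose and 6333 fell. Of its 39 tested members 22 rose, 11 fell and 6 did not pass, with a median log2 fold change of 0.32 (camera adjusted p = 0.104), and adjusted over the list alone 22 rose and 11 fell. The number that fell depended on the scaling, with 26 rising and 4 falling with library size alone and 22 rising and 7 falling with upper-quartile scaling. Pmaip1, which encodes the BH3-only protein NOXA, rose from 18.6 ± 0.194 to 143 ± 5.38 CPM. Tnfrsf10b, a TRAIL death receptor gene, rose from 2.79 ± 0.0478 to 51.3 ± 2.31 CPM, and Apaf1, the scaffold of the apoptosome, from 14.2 ± 1.81 to 58.0 ± 1.45 CPM. Aifm1, which encodes a flavoprotein of the mitochondrial intermembrane space, fell from 153 ± 9.23 to 39.0 ± 0.815 CPM. Among genes of necroptosis, pyroptosis and ferroptosis 11 of 22 rose and 6 fell, also when adjusted over the list alone (camera adjusted p = 0.195), and with library size alone 15 rose and 3 fell. The necroptosis effector Mlkl rose from 3.34 ± 0.487 to 16.8 ± 0.894 CPM, the nucleic acid sensor Zbp1 from 2.59 ± 0.934 to 15.8 ± 0.595 CPM, and Gpx4, which reduces lipid peroxides, fell from 687 ± 1.43 to 429 ± 4.07 CPM. 

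Among called genes with a mean of at least 5 CPM, the 8 largest rises included genes of squamous and injured epithelium. Krt20, a keratin of the urothelium and gut, rose from 0.647 ± 0.302 to 605 ± 13.5 CPM, a log2 fold change of 9.80 (SE 0.12). Sprr2f (ENSMUSG00000050635.1, chromosome 3, 92365187 to 92366442), which encodes a cornified envelope protein, had 519 counts over the cisplatin libraries and 0 over the saline libraries. With 3 counts over the saline group as the floor, the ratio was 149, and the lower end of its 95% counting interval was 121. Sprr1a, of the same multigene family, had a log2 fold change of 7.87 (SE 0.27), the AP-1 subunit Fosl1 of 8.07 (SE 0.25) and the metalloproteinase inhibitor Timp1 of 7.66 (SE 0.24). Zfp365 and 9530053A07Rik had 2 saline counts each. Their ratios were 436 (95% counting interval 120 to 3610) and 342 (94.4 to 2830). Rnu2-10, a U2 small nuclear RNA gene with near-identical copies, was decided by 1 library, since cisplatin stood at 510 ± 719 CPM against 0.714 ± 0.0914 CPM. Without cisplatin replicate 2 its log2 fold change was 0.60 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.337, against at most 0.000543 under the other alternatives). Without saline replicate 2 the log2 fold change was 10.43 for Krt20, 8.79 for Fosl1 and 7.04 for Sprr1a, which stood at 9.17 without saline replicate 1. Zfp365 and 9530053A07Rik went to 7.86 and 7.5 without saline replicate 1, and without saline replicate 2 their saline count was 0.

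The 8 largest falls included sugar and amino acid carriers. Slc2a5 (ENSMUSG00000028976.8, chromosome 4, 150119283 to 150144169), the fructose transporter GLUT5, fell from 121 ± 8.39 to 3.12 ± 0.0589 CPM, a log2 fold change of -5.28 (SE 0.09). Slc7a12, an amino acid transporter gene, fell from 36.2 ± 0.112 to 0.859 ± 0.857 CPM, and Slc35f3, a solute carrier, from 17.9 ± 1.65 to 0.562 ± 0.0784 CPM. Igfbp1, which encodes a binding protein of insulin-like growth factors, fell from 20.9 ± 4.22 to 0.472 ± 0.286 CPM. Clec2h, a C-type lectin gene, fell from 161 ± 5.00 to 4.43 ± 0.00445 CPM and Nepn, which encodes the proteoglycan nephrocan, from 28.9 ± 0.823 to 0.91 ± 0.512 CPM. Gm4477, a gene model, had a log2 fold change of -5.52 (SE 0.27). RP23-3L20.6, annotated as antisense to Egf, stood at -6.30 (SE 0.4), and its reads cannot be told from those of Egf if counting ignored strand. Leaving out cisplatin replicate 1 gave -4.62 for Slc7a12, -6.26 for Igfbp1 and -6.37 for Gm4477. Leaving out cisplatin replicate 2 gave -7.13 for Slc7a12 and -5.70 for Nepn, and leaving out saline replicate 2 gave -5.68 for RP23-3L20.6.

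Transcripts of every tubule segment examined fell on balance, those of the proximal tubule by the most. All 45 tested genes of the proximal tubule fell, 42 of them at least 2-fold, with a median log2 fold change of -2.53 (camera adjusted p = 1.6e-16; adjusted p = 0.172 with an estimated correlation), and adjusted over the list alone 45 fell. Slc34a1 (ENSMUSG00000021490.10, chromosome 13, 55398187 to 55415592) had a log2 fold change of -2.23 (SE 0.06). The lactate transporter Slc5a12 fell from 1088 ± 0.0132 to 41.6 ± 2 CPM, and the neutral amino acid transporter Slc6a19 from 905 ± 25.3 to 52.6 ± 2.13 CPM. Pck1, the gluconeogenic enzyme phosphoenolpyruvate carboxykinase, fell from 2469 ± 9.7 to 222 ± 4.78 CPM. In the thick limb and distal tubule list 24 of 27 genes fell and 2 rose, with a median of -1.36 (camera adjusted p = 3.49e-07; adjusted p = 0.172 with an estimated correlation). Egf, the growth factor precursor gene of these segments, fell from 2331 ± 29.2 to 276 ± 3.78 CPM and the calcium binder Calb1 from 501 ± 15.8 to 55.3 ± 2.68 CPM. In the collecting duct list 18 of 27 fell and 7 rose, with a median of -0.74 (camera adjusted p = 0.012; adjusted p = 0.213 with an estimated correlation). Members active in intercalated cells, the acid-base cells of the duct, had the smallest p. The anion exchanger Slc26a4 fell from 70.2 ± 5.85 to 13.2 ± 1.01 CPM, the ammonia channel Rhcg from 61.5 ± 1.21 to 13.9 ± 0.909 CPM, and the proton pump subunit Atp6v1b1 from 55.8 ± 1.22 to 13.8 ± 0.41 CPM. With library size alone 22 fell and 3 rose in the thick limb and distal tubule list, and 15 fell and 9 rose in the collecting duct list. The counts of both these lists were equal when adjusted over the list alone, and in the same libraries 19 of 25 endothelial markers rose (median 0.85; adjusted p = 0.185 with an estimated correlation).

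Genes of mitochondrial metabolism fell. In the fatty acid oxidation list 29 of 33 genes fell and 2 rose, with a median of -1.04 (camera adjusted p = 2.65e-07; adjusted p = 0.213 with an estimated correlation). Adjusted over the list alone, 30 fell and 2 rose, with library size alone 25 fell and 3 rose, and without cisplatin replicate 1 the number that rose was 1. Ppara, the nuclear receptor that drives this pathway, fell from 91.5 ± 0.234 to 21.6 ± 0.599 CPM and the peroxisomal enzyme Ehhadh from 703 ± 53.7 to 178 ± 0.41 CPM. Pdk4, a kinase that restrains pyruvate dehydrogenase, rose from 18.7 ± 0.28 to 172 ± 2.98 CPM. All 42 nuclear genes of oxidative phosphorylation fell, with a median of -0.93 (camera adjusted p = 7.58e-11; adjusted p = 0.249 with an estimated correlation), and 40 of them fell with library size alone. Ndufs1 of complex I fell from 501 ± 6.46 to 141 ± 3.61 CPM and Atp5a1 of the ATP synthase from 2437 ± 17.5 to 1047 ± 36.8 CPM. All 13 protein-coding genes of the mitochondrial genome fell, 10 of them with library size alone, with a median of -0.89 (camera adjusted p = 0.000988; adjusted p = 0.462 with an estimated correlation). Among them mt-Cytb fell from 4932 ± 543 to 2281 ± 267 CPM. With library size alone the median of these genes was -0.52. The share of mt-Co1 was not lower, at 4.72 and 4.87% of the cisplatin counts against 4.51 and 4.71% of the saline counts. Its fall thus rested on the scaling. Both counts, 42 and 13, stood when adjusted over the list alone. Of the mitochondrial ribosomal RNAs, named after their values were seen, mt-Rnr2 rose from 22683 ± 8317 to 38465 ± 12408 CPM (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.000487), and mt-Rnr1 stood at 3180 ± 1951 and 3869 ± 1391 CPM and did not pass (adjusted p = 0.319 by the same method). Replicates differed widely, with mt-Rnr2 at 3.41 and 5.29% of the cisplatin counts and 2.46 and 1.51% of the saline counts. The libraries were depleted of ribosomal RNA, and whether the depletion was equal between them was not tested. All 45 proximal tubule markers fell in the same libraries as these lists, with a median of -2.53 (adjusted p = 0.172 with an estimated correlation).

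**Figure D2:**
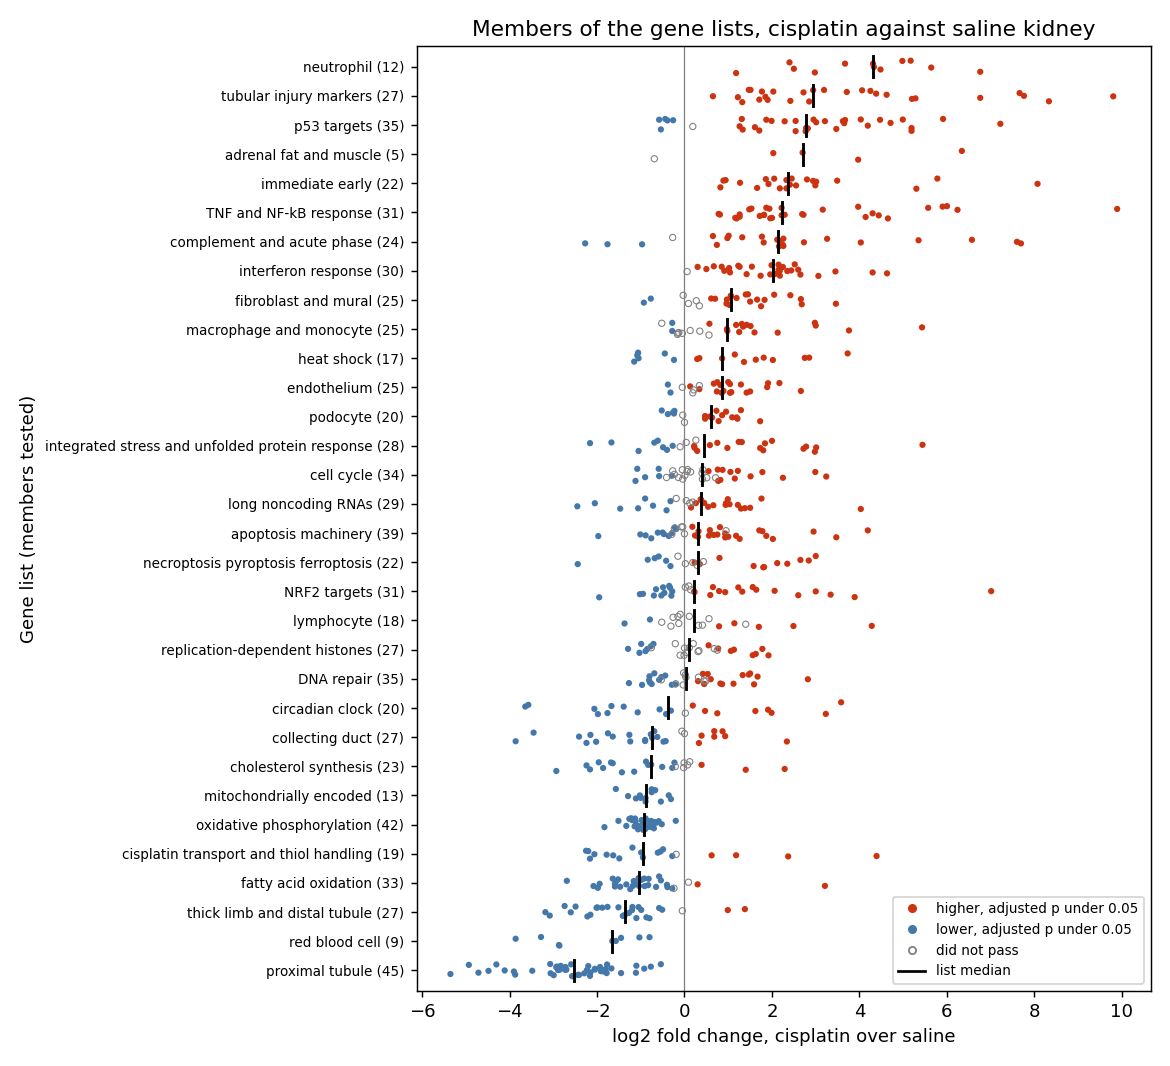
Log2 fold change (cisplatin over saline, x axis) of each tested member of the 32 gene lists (y axis, members tested in brackets), coloured where the adjusted p was under 0.05 (red higher, blue lower) and open where it did not pass, with black bars for list medians. Medians run from -2.53 in the proximal tubule list to 4.32 in the neutrophil list.

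Interferon response genes rose in 29 of 30 cases, with a median of 2.03 (camera adjusted p = 1.67e-09; adjusted p = 0.172 with an estimated correlation). Oasl1, an interferon-induced gene of the oligoadenylate synthetase family, rose from 2.23 ± 0.092 to 55.6 ± 0.215 CPM and the chemokine Cxcl10 from 2.09 ± 0.0527 to 41.6 ± 1.27 CPM. All 22 tested immediate early genes rose, with a median of 2.37 (camera adjusted p = 1.4e-08; adjusted p = 0.185 with an estimated correlation). The transcription factor genes Klf6 and Junb rose from 49.9 ± 1.57 to 292 ± 9.58 CPM and from 20.4 ± 0.436 to 108 ± 2.18 CPM. In the complement and acute phase list 20 of 24 genes rose and 3 fell, with a median of 2.14 (camera adjusted p = 0.000118; adjusted p = 0.185 with an estimated correlation). Serpina3n, an acute phase protease inhibitor, rose from 0.231 ± 0.0208 to 22.6 ± 0.00839 CPM and Socs3, an inhibitor of cytokine signalling, from 2.99 ± 0.405 to 49.5 ± 0.971 CPM, whereas complement factor gene Cfb fell from 390.5 ± 4.30 to 115 ± 2.52 CPM. Adjusted over the list alone, 29, 22 and 20 rose in these lists and 0, 0 and 3 fell. In the same libraries 12 of 12 tested neutrophil markers rose (median 4.32; adjusted p = 0.249 with an estimated correlation), as did 15 of 25 macrophage and monocyte markers (median 0.98; adjusted p = 0.21 with an estimated correlation).

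Markers of macrophages, neutrophils, endothelium, and fibroblasts and mural cells mostly rose. Macrophage and monocyte markers rose in 15 of 25 cases and fell in 2, with a median of 0.98 (camera adjusted p = 0.00501; adjusted p = 0.21 with an estimated correlation). Without cisplatin replicate 1 the number that fell was 1, and without cisplatin replicate 2 it was 3. Cd68, a lysosomal glycoprotein gene, rose from 1.62 ± 0.0851 to 69.7 ± 8.92 CPM and the endotoxin co-receptor Cd14 from 4.47 ± 0.181 to 35.1 ± 0.00103 CPM. All 12 tested neutrophil markers rose, with a median of 4.32 (camera adjusted p = 0.000209; adjusted p = 0.249 with an estimated correlation). The list held 20 genes, and the others were not tested. S100a9, a calcium-binding protein gene of neutrophils, rose from 0.414 ± 0.18 to 8.10 ± 0.000351 CPM and the chemokine receptor Cxcr2 from 2.47 ± 0.483 to 12.9 ± 0.731 CPM. Endothelial markers rose in 19 of 25 cases and fell in 2, with a median of 0.85 (camera adjusted p = 0.000268; adjusted p = 0.185 with an estimated correlation). Plat, which encodes tissue plasminogen activator, rose from 78.5 ± 4.47 to 354 ± 9.33 CPM and the endothelial cadherin Cdh5 from 36.3 ± 3.03 to 88.4 ± 0.189 CPM. Fibroblast and mural cell genes rose in 19 of 25 cases and fell in 2, with a median of 1.06 (camera adjusted p = 2.78e-05; adjusted p = 0.185 with an estimated correlation). The collagen gene Col3a1 rose from 74.2 ± 3.73 to 396 ± 3.60 CPM, and Lox, a collagen-crosslinking enzyme, from 5.21 ± 0.359 to 57.1 ± 3.42 CPM. Adjusted over the list alone, the counts of these 4 lists were unchanged. With library size alone 20 macrophage, 12 neutrophil, 22 endothelial and 21 fibroblast and mural genes rose, and 0, 0, 0 and 1 fell. These rises are relative, and all 45 tested proximal tubule genes fell in these libraries, with a median of -2.53.

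Podocyte genes rose in 13 of 20 cases and fell in 5, both over all genes and adjusted over the list alone, with a median of 0.61 (camera adjusted p = 0.0515). Without cisplatin replicate 2 the number that fell was 3, and with library size alone it was 0. Nes, which encodes the intermediate filament protein nestin, rose from 44.8 ± 1.47 to 109.9 ± 2.65 CPM. Lymphocyte markers rose in 5 of 18 cases and fell in 2, and adjusted over the list alone 3 rose and 2 fell (camera adjusted p = 0.602). Without cisplatin replicate 1 or saline replicate 2, 3 rose, and the number that fell was 1 without cisplatin replicate 2 and 3 without saline replicate 2. Cd4 rose from 0.407 ± 0.113 to 1.30 ± 0.231 CPM and the immunoglobulin heavy chain gene Ighm fell from 4.78 ± 0.0444 to 2.75 ± 0.253 CPM. With library size alone Ighm did not pass (log2 fold change -0.43, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0582, against 0.000148 to 0.018 under the other alternatives). All 9 tested red blood cell genes fell, with a median of -1.65 (camera adjusted p = 0.000728; adjusted p = 0.188 with an estimated correlation), and adjusted over the list alone 9 fell. Slc4a1, a bicarbonate exchanger that intercalated cells also express, fell from 25.2 ± 4.36 to 1.72 ± 0.251 CPM and the beta-globin gene Hbb-bs from 79.3 ± 3.86 to 29.1 ± 0.501 CPM, although reads can be shared between globin copies. Of 5 tested genes for adrenal, fat and muscle, which border the kidney, 4 rose, also adjusted over the list alone (camera adjusted p = 0.065). The list held 21 genes, and the others were not tested. Mc2r and Cidec, with 1 and 3 saline counts, passed the filter through the cisplatin libraries, which had 22 and 303 counts. The share that rose thus depends in part on the filter. Plin4, a lipid droplet gene of fat, rose from 1.71 ± 0.267 to 11 ± 0.444 CPM and the steroidogenic transport gene Star from 0.796 ± 0.207 to 3.33 ± 0.239 CPM.

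Stress pathways linked to cisplatin moved in both directions, as did all 17419 tested genes, of which 6487 rose and 6333 fell. Of the lists given here, camera at the preset correlation called only that of cisplatin transport and thiol handling. In the list of NRF2 targets, the antioxidant response, 16 of 31 genes rose and 12 fell (median 0.22, camera adjusted p = 0.256), and with library size alone 19 rose and 5 fell. The heme oxygenase gene Hmox1 rose from 9.34 ± 1.57 to 95.7 ± 4.66 CPM and the sulfiredoxin gene Srxn1 from 54.6 ± 1.36 to 330.02 ± 1.02 CPM. Genes of cisplatin transport and thiol handling fell in 14 of 19 cases and rose in 4, with a median of -0.95 (camera adjusted p = 0.0149; adjusted p = 0.381 with an estimated correlation). Slc47a1, the efflux transporter MATE1, fell from 631 ± 18.3 to 184 ± 0.592 CPM, and the metallothionein gene Mt2 rose from 8.33 ± 1.9 to 177 ± 8.56 CPM. Slc47a1 also stands in the proximal tubule list, of which all 45 tested genes fell (median -2.53; adjusted p = 0.172 with an estimated correlation). DNA repair genes rose in 14 of 35 cases and fell in 12 (median 0.03, camera adjusted p = 0.649), and with library size alone 20 rose and 7 fell. Ercc1, an endonuclease subunit of nucleotide excision repair, rose from 7.07 ± 0.0961 to 50.1 ± 2.81 CPM, whereas the damage kinase gene Atm fell from 83.4 ± 2.84 to 34.5 ± 0.784 CPM. Cell cycle genes rose in 13 of 34 cases and fell in 6 (median 0.40, camera adjusted p = 0.141), and adjusted over the list alone 13 rose and 5 fell, while with library size alone 18 rose and 3 fell. Ccne2, a cyclin gene, and Cdt1, which encodes a replication licensing factor, rose from 2.44 ± 0.315 to 19.6 ± 0.556 CPM and from 1.93 ± 0.41 to 18 ± 1.79 CPM, whereas the cyclin D1 gene Ccnd1 fell from 263 ± 0.451 to 174 ± 3.10 CPM. Integrated stress and unfolded protein response genes rose in 17 of 28 cases and fell in 8 (median 0.44, camera adjusted p = 0.0618), and with library size alone 20 rose and 5 fell. The transcription factor gene Atf3 rose from 1.50 ± 0.135 to 66.1 ± 1.62 CPM and Herpud1, of endoplasmic reticulum protein degradation, fell from 290.2 ± 4.96 to 65.1 ± 3.63 CPM. Of 17 heat shock genes 11 rose and 6 fell (median 0.86, camera adjusted p = 0.149), among them Hspb1, a small chaperone gene, which rose from 3.63 ± 0.148 to 48.1 ± 1.97 CPM. Adjusted over the list alone, the counts of these lists other than the cell cycle list were unchanged.

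Long noncoding RNAs, the class the series' title names, changed in both directions. So did the 17419 tested genes of all types, of which 6487 rose and 6333 fell. Of 567 tested lincRNA genes 216 rose and 126 fell, 168 and 90 of them at least 2-fold, and with library size alone 291 rose and 90 fell. Of 379 antisense genes 123 rose and 95 fell, against 172 and 74 with library size alone. In the list of known long noncoding RNAs 17 of 29 rose and 8 fell, also adjusted over the list alone (median 0.37, camera adjusted p = 0.149). Neat1, the scaffold of paraspeckles, rose from 434 ± 3.81 to 1015 ± 4.82 CPM, and Malat1, an abundant nuclear RNA, from 20472 ± 197 to 29811 ± 679 CPM. Snhg11, a small nucleolar RNA host gene, fell from 54.0 ± 2.61 to 19.6 ± 1.81 CPM. Malat1 held 3.37 and 3.39% of the cisplatin counts and 1.77 and 1.83% of the saline counts. Saline replicate 1 stood apart in Yam1, a ribosomal RNA-like row, with 2.02% of its counts against 0.08 to 0.15% in the other libraries. Other such rows differed by group. Gm26917, treated here as a ribosomal RNA row, held 0.74 and 0.77% of the cisplatin counts and 0.17% of the counts of each saline library. Rows of rRNA type held 0.03 and 0.04% of the cisplatin counts and 0.40 and 0.19% of the saline counts. Without saline replicate 1, 12504 genes were called, and without ribosomal RNA rows 12822, an alternative chosen after seeing the data.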

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

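The tests without ribosomal RNA rows, on protein-coding genes alone and against a 2-fold change were chosen after the results were seen. Across the other scalings, filters and tests, 11023 (DESeq2) to 13336 (no low-count filter) genes were called, against 12820. Leaving out each library in turn gave 11490 to 12504 called genes, 5734 to 6209 at 2-fold, and 20 to 21 lists. A lone library was then assumed to vary like the other group. At 2-fold, limma-trend on FPKM with a pseudocount of 1 called 2860 genes against 6148, where the pseudocount shrinks folds of weakly expressed genes, and 6068 with a pseudocount of 0.1. The test against a 2-fold change called 4245. Ribosomal RNA rows left out gave 12822 genes, and protein-coding genes alone 11293. With library size alone 135 called genes were called with the other sign. Replicate numbers did not pair the libraries, since same-numbered deviations correlated at -0.02. The replicate block gave 12653 genes, 6102 at 2-fold and 19 lists. Camera with an estimated correlation called 0 lists against 19, with 8 at an unadjusted p under 0.05. Correlation between genes does not account for this in the proximal tubule list, where the estimate of 0.01 equalled the preset. In the simulation, whose genes were drawn independently, the same change of setting took camera's p for a raised list from 9.9e-45 to 0.00449. Of 200 unchanged lists there, 3 had p under 0.05 at the preset and 0 with an estimate. Calls lost with an estimated correlation thus need not come from correlation between genes, and their cause was not tested further. Under the other alternatives camera called 19 to 21 lists. The podocyte, stress response, and adrenal, fat and muscle lists also passed in 5, 3 and 2 fits. Of 145 named genes none changed direction in the alternatives that tested it, at most 14 and not on FPKM, and Rnu2-10 (0.60 without cisplatin replicate 2) and Ighm (-0.43 with library size alone) lost their calls. Depth limits genes with few saline counts, such as Tnf and Zfp365.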

Other observations

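The tests of nephron segments and of GC content were chosen after the results were seen. Clock genes fell in 11 of 20 cases and rose in 8, also adjusted over the list alone (median log2 fold change -0.37, camera adjusted p = 0.331), and with library size alone 8 fell, 9 rose and the median was 0. The members with the smallest p were output regulators and a repressor of the clock. Dbp and Hlf, PAR bZIP transcription factor genes, fell from 111 ± 0.41 to 9.39 ± 0.688 CPM and from 104 ± 0.774 to 8.34 ± 0.556 CPM (SD, n = 2). Tef, of the same family, fell from 366 ± 10.4 to 115 ± 1.05 CPM and the repressor gene Nr1d2 from 327 ± 7.68 to 96.6 ± 4.72 CPM. The hour of tissue collection is not given in the sources used here. Cholesterol synthesis genes fell in 15 of 23 cases and rose in 3, also adjusted over the list alone, or 12 and 7 with library size alone, with a median of -0.76 (camera adjusted p = 0.00501; adjusted p = 0.262 with an estimated correlation). Cyp51, which encodes lanosterol demethylase, fell from 526 ± 14 to 68.9 ± 2.77 CPM and Hmgcs1, a synthase early in the pathway, from 769 ± 13.4 to 197 ± 8.95 CPM. In the same libraries all 45 tested proximal tubule genes fell (median -2.53; adjusted p = 0.172 with an estimated correlation). Replication-dependent histone genes rose in 8 of 27 cases and fell in 7, also adjusted over the list alone (median 0.11, camera adjusted p = 0.885), and 15 rose with library size alone. Hist1h4c fell from 121 ± 5.47 to 49.6 ± 2.86 CPM, although reads can be shared between histone copies.

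Genes with a long genomic span had lower log2 fold changes after cisplatin. Over 14411 protein-coding genes, which are not independent replicates, Spearman's rho with span was -0.236 (95% bootstrap interval -0.251 to -0.22), and median log2 fold changes ran from 0.26 in the fifth of genes with a median span of 4.6 kb to -0.43 in that of 127.1 kb. With exonic length fixed the partial rho stayed at -0.232, and with GC content fixed at -0.186, which argues against GC content as the whole cause. The partial rho with exonic length was 0.082 with span fixed, under the absolute bound of 0.1 set beforehand for RNA fragmentation. It was 0.147 with abundance and GC content fixed as well, so fragmentation stays open for that opposite trend. With exonic length, abundance and GC content fixed the span trend was -0.222, so annotated exonic length did not account for it. The lengths of the transcripts present were not measured, so fragmentation acting through those was not tested. A candidate explanation is lower transcript output from long genes, on which cisplatin adducts could stall RNA polymerase, but a changed cell makeup with other gene lengths was not tested and stays open.

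Proximal tubule transcripts fell more than those of the thick limb and distal tubule (difference of medians -1.17, two-sided permutation p = 0.0001, adjusted p = 0.00017 over 7 comparisons), whereas the latter and the collecting duct did not differ after adjustment (-0.62, p = 0.045, adjusted p = 0.052). The permutations shuffled genes between lists. Genes are not independent replicates, so these p-values describe the spread between genes and not that between libraries or animals. A lower share of proximal tubule cells alone would move the other cell types alike, but endothelial and thick limb medians differed by 2.21 on the log2 scale (permutation p = 2e-05, the smallest that 100000 resamples give, adjusted p = 4.7e-05). An equal loss of transcripts from all segments, with no other change, is argued against by the proximal tubule and collecting duct medians. They differed by -1.79 (permutation p = 2e-05, adjusted p = 4.7e-05). The difference cannot tell an unequal loss of cells from an equal loss joined by changes within cells. Within the proximal tubule list, 84.7% of 990 pairs of transcripts differed by over 3 standard errors, from -5.35 for Slc7a12 to -0.54 for Slco1a1, named after its value was seen. These standard errors describe the spread of 2 libraries per group, and no other list was compared. The share of pairs thus cannot tell whether a fall specific to each transcript contributed. Such a fall, loss of cells of several segments to different degrees, and a change within endothelial cells all stay open.

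Of 134 sense intronic genes 63 rose and 12 fell after cisplatin, and lincRNA genes also rose more often than they fell, whereas of 195 snoRNA genes 22 rose and 45 fell (68 and 12 with library size alone). The sense intronic transcripts did not follow the exons of their host genes, since over 123 pairs with 93 host genes, up to 11 pairs sharing a host, the intronic transcript lay above its host by a median of 0.84 (95% bootstrap interval over host genes 0.73 to 1.0). The pairs were not matched on abundance, so this difference may hold a trend with abundance. Low abundance may account for the rise, since the median of 0.66 lay at percentile 94.1 of 10000 abundance-matched protein-coding lists. Their medians centred on 0.44, with a central 95% of 0.19 to 0.7, the range set beforehand for this explanation. A rise peculiar to sense intronic transcripts is thus not shown. Genomic DNA in the cisplatin libraries cannot be told apart, although RNA was treated with DNase: counts of 174 olfactory and vomeronasal receptor genes had a cisplatin to saline ratio of 1.41 relative to library totals (95% interval 1.34 to 1.49), under the bound of 1.5 set beforehand. That bound was not decisive because Olfr613, named after its value was seen, held 2824 of their 5308 counts, and the 163 receptor genes with under 50 counts gave 1.67 (1.42 to 1.97), while after TMM scaling, the scale of the fold changes, the ratios were 1.1 (1.04 to 1.16) for all 174 and 1.3 (1.1 to 1.53) for the 163.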
